A study of Mus musculus with 12 samples.

How the data were processed

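Total RNA from the frontal cortex of 12 C57BL/6 mice was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin. The deposited table holds log2 probe-set signal for 34760 probe sets on each of the 12 arrays. How the authors corrected background, normalized between arrays and summarised probes is not given in the sources used here. The values themselves show that the arrays had already been brought to a common level. Their medians lay between 6.95 and 7.01 on the log2 scale, and single values between 1.47 and 14.11. A background correction that was incomplete would compress the change of dim genes, and a normalization that equalises arrays would hide a change shared by most genes. No detection calls, scan dates or slide numbers were used, so neither a detection limit nor a hybridization batch could be tested. For arrays, their number limits the precision.

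Probe sets were named from the platform's annotation table. Of the 34760 probe sets, 21640 named exactly 1 gene, 1321 named several genes and 11799 were unnamed in that table. Entrez identifiers of 21553 of the 21640 probe sets matched the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Probe sets naming several genes were left out of gene-level tests. For the 954 genes with several probe sets, the one with the highest mean over all 12 mice was taken. This gave 19937 genes, with no filter on dim genes. The deposited table names no genome build, so no coordinates are given.

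Ages came from the labels, which give 11 ages with 2 mice at 2 days and 1 mouse at every other age. The mice were placed in an immature stage (2 to 32 days, 6 mice) and an adult stage (61 to 904 days, 6 mice). In limma 3.58.1 (R 4.3.3), 1 linear model of all 12 mice gave each stage its own intercept and its own slope on log2 age, leaving 8 residual degrees of freedom. The development trend is the slope of the immature stage and the adult trend that of the adult stage. Each is printed as the fitted log2 change over its window, the slope times 4 doublings of age from 2 to 32 days or 3.89 doublings from 61 to 904 days, ± its SE. The slope difference is the adult slope minus the development slope, in log2 units per doubling of age. The stage contrast is the mean of the 6 adult mice minus that of the 6 immature mice. Curvature is the quadratic coefficient of centred log2 age over all 12 mice, in which a negative value means a level highest at intermediate ages or a rise that flattens. All tests were moderated by eBayes, two-sided, and adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The reversal share is the percentage of genes called in the development trend whose adult slope has the opposite sign.

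Before the data were examined, 27 gene lists with 487 genes were fixed. Of these genes, 432 were measured and 55 were not. Each list with at least 5 measured genes was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists. Genes named in the text follow a rule fixed at the same time. It takes the 6 genes with the highest and the 6 with the lowest coefficient among those called in each comparison, or, where fewer passed, those with the smallest p, named as not passing. It adds up to 4 genes with the smallest p in each list, and a fixed set (Grin2a, Grin2b, Slc12a5, Slc12a2, Mbp, Dcx, Gfap, Pvalb, C4b, Scn1a, Scn3a, Gapdh, Actb, Hprt, and Xist with 4 Y-linked genes). Gapdh had only probe sets that name several genes, and the annotation table does not name the Y-linked Ddx3y. C1qa, C1qb, C1qc, Homer1 and Tnr each stand in 2 lists.

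The fits were tested on simulated data with 200 changed genes among 19937. A change of 1 on the log2 scale over the window was recovered for 77.6% of changed genes in the development trend and for 77.6% in the adult trend. A change of 2 was recovered for 100% in both, and a change of 0.5 for 40.3% and 35.8%. For the slope difference, sizes were set as a change over the adult window, not per doubling of age. At sizes of 0.5, 1 and 2 on that scale, 5.97%, 50.7% and 87.9% of changed genes were recovered, so these fits can miss smaller changes. The simulated noise was independent between genes, while the real arrays shared an axis of differences, described below. With 200 changed genes the adjusted cutoff is also easier to pass than where few genes change. In the real adult trend C4b, at 2.41 ± 0.32, did not pass. The recovered shares therefore set no bound on the adult changes that were missed. Alternatives were quantile normalization of the values again, dropping the dimmest 1/3 of genes, all probe sets in place of genes, eBayes with trend and robust options, array weights, age in days, another border between the stages, fits of single stages, and leaving out mice singly or in pairs. A covariate for an array axis unrelated to age, and the removal of the mice of 649 and 904 days or of 122 and 184 days, were chosen after seeing the data, as were list tests without single mice. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.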

Results

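Gene expression was measured in the frontal cortex of 12 C57BL/6 mice, a standard inbred laboratory strain, aged 2, 5, 11, 20, 32, 61, 122, 184, 365, 649 and 904 days. The series addressed how cortical expression changes as the brain matures after birth and into old age. Separate mice of the same age existed only at 2 days (n = 2), so every other age rests on 1 mouse and the comparisons use trends with age. Over genes, the median SD between the 2-day mice was 0.0943 on the log2 scale and the 90th percentile was 0.266. Their arrays correlated with r = 0.988 across probe sets, which are not independent replicates. This r was not the highest: 2-day replicate 2 had r = 0.991 with the 5-day mouse, and the highest of any pair was 0.993. The 2-day mice also differed in sex-linked signal, given next, so their SD is not one between like mice.

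All 12 mice carry the label male, and the sex-linked genes went against it on 11 arrays. Xist, the RNA that silences the second X chromosome of female cells, had a log2 signal of 10.75 to 11.61 on those 11 arrays and 5.67 in 2-day replicate 2. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 9.43, 8.60 and 8.95 in 2-day replicate 2, against medians of 3.18, 4.69 and 3.70 on the other 11 arrays. The array with Y-linked signal is one of the 2 youngest, so the sex of the mice and age are confounded for sex-linked genes. Xist gave a development change of 2.18 ± 1.38 with all mice, 4.26 without 2-day replicate 1 and -0.92 without replicate 2 (limma adjusted p = 0.268, 0.0208 and 0.000213).

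**Figure D1:**
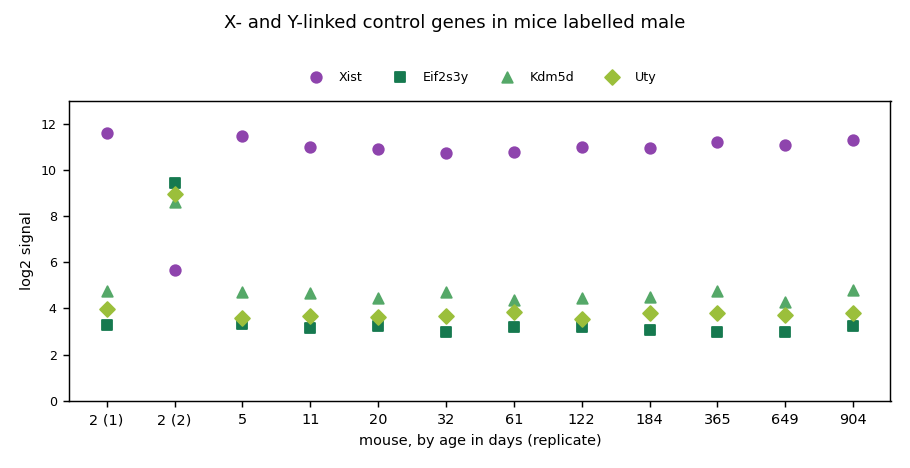
Log2 signal of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 12 arrays, ordered by age in days with the replicate number in parentheses at 2 days. Points are single mice; 2-day replicate 2 has low Xist (5.67) and high Y-linked signal, and the other 11 arrays have the opposite.

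The development trend asks which genes change from 2 to 32 days. Most listed genes of myelin, synapses, ion channels and astrocytes rose, while most of those of dividing cells and of immature neurons fell. As whole lists, none passed in camera with an estimated correlation. The gene with the highest fitted rise was Lamp5, a neuronal member of the lysosome-associated membrane protein family, from 5.68 and 6.34 in the 2-day mice to 10.99 at 32 days, a change of 5.43 ± 0.31 (43.2-fold). Mag, a myelin adhesion protein, rose 29.2-fold, and Fam107a, the sodium channel subunit Scn4b and the endothelial transporter Slco1a4 rose 19.8-, 18.0- and 17.1-fold, and the myelin gene Mobp by 4.25 ± 0.62. Trim67 fell from 11.44 in both 2-day mice to 7.31 at 32 days (25.3-fold lower as fitted), followed by B3gnt5 with -4.42 ± 0.34, Mex3a with -3.89 ± 0.28, the polysialic acid synthase St8sia2 with -3.78 ± 0.32, the matrix glycoprotein Tnc with -3.69 ± 0.31 and Vash2 with -3.67 ± 0.24. In limma, adjusted p was at most 0.000137 for each of these 12 genes. In all, 7244 of 19937 genes passed, 3518 higher and 3726 lower with age, and 1018 of the risen and 751 of the fallen genes changed at least 2-fold over the window.

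Genes of proliferating cells and young neurons fell together. In the cell division list 21 of 23 measured genes fell and 0 rose, including the ribonucleotide reductase subunit Rrm2 (-2.10 ± 0.16) and the mitotic kinesin Kif11 (-2.42 ± 0.25; camera adjusted p = 4.56e-12, and adjusted p = 0.124 with an estimated correlation). Among genes of immature neurons and axon growth 21 of 22 fell, with Sox11 at -3.63 ± 0.25, Igfbpl1 at -3.10 ± 0.20, Sox4 at -2.91 ± 0.15 and Dcx, a microtubule protein of migrating neurons, at -2.80 ± 0.22 (camera adjusted p = 1.33e-13; adjusted p = 0.0939 with an estimated correlation). Of 15 cortical layer transcription factors 12 fell and 0 rose, led by Neurod6 at -2.23 ± 0.21 (camera adjusted p = 2.55e-06; adjusted p = 0.0705 with an estimated correlation). Of 11 imprinted and related growth genes 6 fell, including Igf2bp3 (-2.06 ± 0.16) and Nnat (-1.97 ± 0.22), and Peg3 rose by 1.28 ± 0.16 (camera adjusted p = 0.0058; adjusted p = 0.184 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 18 cases, among them Lss (-1.35 ± 0.17) and Cyp51 (-1.20 ± 0.14), and the isomerase Ebp, named after its value was seen, rose by 0.62 (camera adjusted p = 4.29e-06; adjusted p = 0.202 with an estimated correlation). The counts adjusted over the list alone were 22 cell division genes and 8 imprinted growth genes lower, and the other 3 lists had equal counts.

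Glial genes rose. All 19 measured myelin and mature oligodendrocyte genes rose, with Ugt8a at 3.94 ± 0.33 and Mbp, a main protein of compact myelin, at 3.48 ± 0.28 (camera adjusted p = 4.56e-12; adjusted p = 0.111 with an estimated correlation). Of 14 oligodendrocyte precursor genes 8 rose and 6 did not pass (camera adjusted p = 0.00469, and adjusted p = 0.347 with an estimated correlation). Those that rose included Enpp6 at 2.45 ± 0.38 and Bcas1 at 2.35 ± 0.26, taken below as markers of newly forming oligodendrocytes, and Olig1 at 0.42 ± 0.09. Astrocyte genes rose in 17 of 18 cases, including Aldoc (2.26 ± 0.17) and the tight junction gene Cldn10 (1.96 ± 0.15; camera adjusted p = 7.49e-11, and adjusted p = 0.0862 with an estimated correlation). Microglia genes rose in 16 of 18, with the protease Ctss at 2.45 ± 0.26 and the growth factor receptor Csf1r at 1.79 ± 0.19 (camera adjusted p = 1.11e-08; adjusted p = 0.129 with an estimated correlation). In the complement and MHC class I list, which shares C1qa, C1qb and C1qc with the microglia list, 6 of 12 rose, among them B2m by 1.56 ± 0.19 (camera adjusted p = 0.00216; adjusted p = 0.202 with an estimated correlation). Endothelial genes moved both ways, with 7 of 15 higher and 4 lower (camera adjusted p = 0.179), as did genes of pericytes and fibroblasts, with 1 of 19 higher and 6 lower (0.122). Interferon response genes rose in 5 of 16 cases, and the list did not pass (0.116). When adjusted over the list alone, 7 complement and MHC genes rose and 7 pericyte and fibroblast genes fell, with no other count different among these lists.

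Neuronal signalling genes rose as well. Of 21 presynaptic genes 20 rose, including Sv2b (2.28 ± 0.13) and Snap25 (1.96 ± 0.10), and Slc17a6, the vesicular glutamate transporter VGLUT2, named after its value was seen, fell by 1.26 (camera adjusted p = 3.43e-12; adjusted p = 0.0705 with an estimated correlation). Glutamate receptor and postsynaptic genes rose in 13 of 21 cases, with Camk2a at 3.17 ± 0.23, Cacng3 at 2.58 ± 0.20 and the NMDA receptor subunit Grin2a at 2.47 ± 0.16 (camera adjusted p = 3.13e-06; adjusted p = 0.143 with an estimated correlation). Another NMDA receptor subunit, Grin2b, had a change of -0.08 ± 0.10 and did not pass (limma adjusted p = 0.624). GABA receptor and chloride transporter genes rose in 11 of 14 cases (camera adjusted p = 4.29e-06; adjusted p = 0.124 with an estimated correlation). There, the chloride exporter Slc12a5 rose by 1.93 ± 0.12, and the importer Slc12a2 had a change of 0.28 ± 0.11 (limma adjusted p = 0.0556). Among sodium and potassium channels 18 of 20 rose, with Scn2b at 3.43 ± 0.18 and Scn1a at 1.597 ± 0.125, and Scn3a fell by 1.06 ± 0.14 (camera adjusted p = 1.07e-10; adjusted p = 0.0705 with an estimated correlation). Interneuron markers split into 11 that rose, including Calb1 (3.18 ± 0.35) and Pvalb (2.80 ± 0.40), and 5 that fell out of 22 (camera adjusted p = 0.0322; adjusted p = 0.291 with an estimated correlation). Activity-regulated genes rose in 16 of 23 cases, with Egr1 at 2.04 ± 0.23 (camera adjusted p = 2.52e-06; adjusted p = 0.202 with an estimated correlation). Among genes adjusted over the list alone, 14 glutamate receptor genes rose and 2 fell, 12 GABA receptor genes rose and 17 activity-regulated genes rose.

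Matrix, energy and stress genes changed too. In the perineuronal net and brain matrix list 6 of 14 genes rose and 6 fell: Vcan and Has2 fell by 2.90 ± 0.22 and 2.55 ± 0.19 and Sparcl1 rose by 1.10 ± 0.11. That list's median was 0.20, its mean -0.25 and its test pointed down without passing (camera adjusted p = 0.872). Oxidative phosphorylation genes rose in 19 of 24 cases, with Sdha at 0.84 ± 0.10 (camera adjusted p = 6.44e-08; adjusted p = 0.143 with an estimated correlation). Glycolysis genes rose in 9 of 12, including Eno2 (2.43 ± 0.14) and Aldoa (1.85 ± 0.10; camera adjusted p = 2.07e-06, and adjusted p = 0.0705 with an estimated correlation), and the hexokinase Hk1, named after its value was seen, fell by 0.27. Stress and chaperone genes rose in 6 of 14, led by the metallothioneins Mt1 (2.52 ± 0.25) and Mt2 (2.48 ± 0.26; camera adjusted p = 0.00308, and adjusted p = 0.143 with an estimated correlation). Of the lists for tissue outside the cortex, striatum markers rose in 8 of 10 cases, including Penk (4.08 ± 0.42) and Rasd2 (3.50 ± 0.23; camera adjusted p = 3.99e-05, and adjusted p = 0.15 with an estimated correlation). Blood cell genes (0 of 6 called, camera adjusted p = 0.635) and choroid plexus and ependyma markers (0 of 12 called, camera adjusted p = 0.763) did not pass. Of the 4 measured sex check genes 0 passed. With p adjusted over the list alone, 20 oxidative phosphorylation, 7 stress and 9 striatum genes rose and 3 sex check genes fell. Of the control genes, Hprt rose by 0.96 ± 0.12 and Actb had a change of -0.37 ± 0.09, which lost its call after quantile normalization and without the mouse of 32 days and 1 mouse of 2 days.

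**Figure D2:**
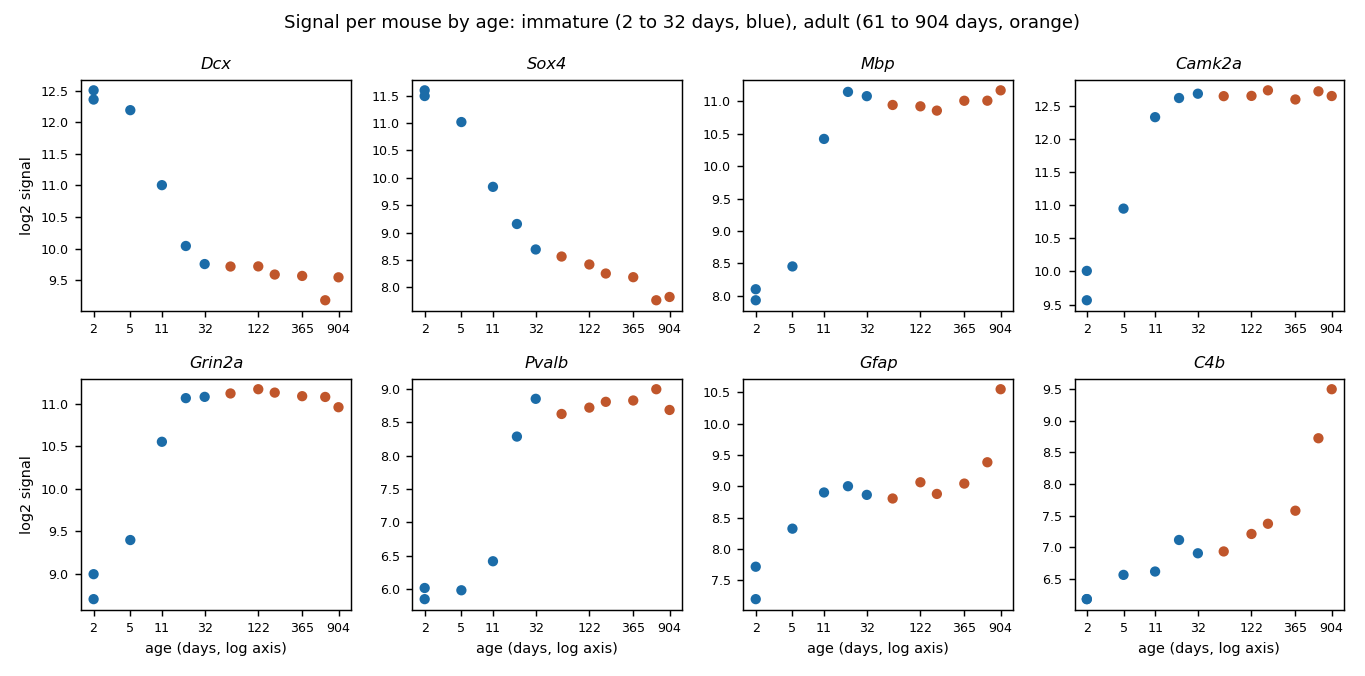
Log2 signal of 8 genes in each of the 12 mice against age in days on a log axis, with immature mice in blue and adult mice in orange. Dcx and Sox4 decline and Mbp, Camk2a, Grin2a and Pvalb climb up to 32 days, and Gfap and C4b are highest at 904 days (10.55 and 9.50).

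The adult trend asks what changes from 61 to 904 days, in young to late adulthood. The genes with the smallest p were Pcdhb2, a clustered protocadherin of neuronal cell contacts, and C4b, a complement component, and neither passed. C4b signal was 6.94 at 61 days, 7.58 at 365, 8.72 at 649 and 9.50 at 904 days, a fitted change of 2.41 ± 0.32 (5.31-fold; limma adjusted p = 0.0513). The closely related gene C4a had a change of 0.35 ± 0.28, and signal shared between their probes was not excluded. Pcdhb2 had 1.27 ± 0.16 (limma adjusted p = 0.0513), Abca8a 1.16 ± 0.18 (0.174), and the alarmin Il33 1.21 ± 0.21 (0.254). Among lower genes, the neuronal precursor factor Sox4 had -0.81 ± 0.16 (0.39) and the endoplasmic reticulum proteins Manf and Pdia4 -0.49 ± 0.11 (0.569) and -0.57 ± 0.13 (0.676). Gfap, the astrocyte filament protein, had 1.32 ± 0.38 (0.977), with 8.81 at 61 days and 10.55 at 904 days.

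By limma, 0 of 19937 genes passed in the adult trend, and 810 had an unadjusted p under 0.05. Uniform p-values would give 997, while 100 orders of the adult ages gave a median of 461, and 27 of them gave as many as 810. Other settings called 0 to 5 genes, except array weights, which called 528 and gave the 61-day array a weight of 5.55. The adjusted p of C4b ranged from 0.000353 (age in days) to 1 over 24 alternatives. Leaving out single mice, C4b passed without the 365-day mouse (0.00475), and C4b, Pcdhb2, Abca8a, Spag6 and Sox4 passed without the 5-day mouse (0.0407 to 0.0494). With the preset correlation, camera called 10 of 26 lists in the adult trend, although 0 of their members passed alone over all genes. Complement and MHC class I genes shifted up with a median change of 0.38 (adjusted p = 1.64e-10; adjusted p = 0.206 with an estimated correlation). Microglia genes shifted up with a median of 0.36, led by Lyz2 at 1.57 ± 0.35 (camera adjusted p = 2.81e-08; adjusted p = 0.574 with an estimated correlation). Interferon response genes (median 0.22, camera adjusted p = 0.00102) and myelin genes (0.21, 0.0139) also shifted up, with adjusted p = 0.574 and adjusted p = 0.662 with an estimated correlation. Of the 10 lists, 6 shifted down: immature neurons (median -0.15, camera adjusted p = 1.95e-05), endothelial cells (-0.15, 0.00102), cell division (-0.16, 0.00568), glutamate receptors and postsynaptic density (-0.11, 0.00568), striatum markers (-0.20, 0.00959) and interneuron markers (-0.11, 0.0239). Their adjusted p with an estimated correlation was 0.662 for cell division and 0.574 for the others. After quantile normalization again the glutamate receptor and interneuron lists no longer passed (camera adjusted p = 0.104 and 0.0959), and cholesterol synthesis did (0.0118). The myelin list no longer passed without the mice of 122 and 184 days (0.094). Adjusted over the list alone, 3 complement and MHC genes and 3 microglia genes were higher, 2 immature neuron genes and 1 stress gene lower, and 0 passed in the remaining lists. Without the mouse of 904 days 6 lists passed, 5 of these and cholesterol synthesis. Without those of 649 and 904 days only cell division did. Striatum markers then had a mean change of 0.12, with the slope scaled to the full window of 61 to 904 days.

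**Figure D3:**
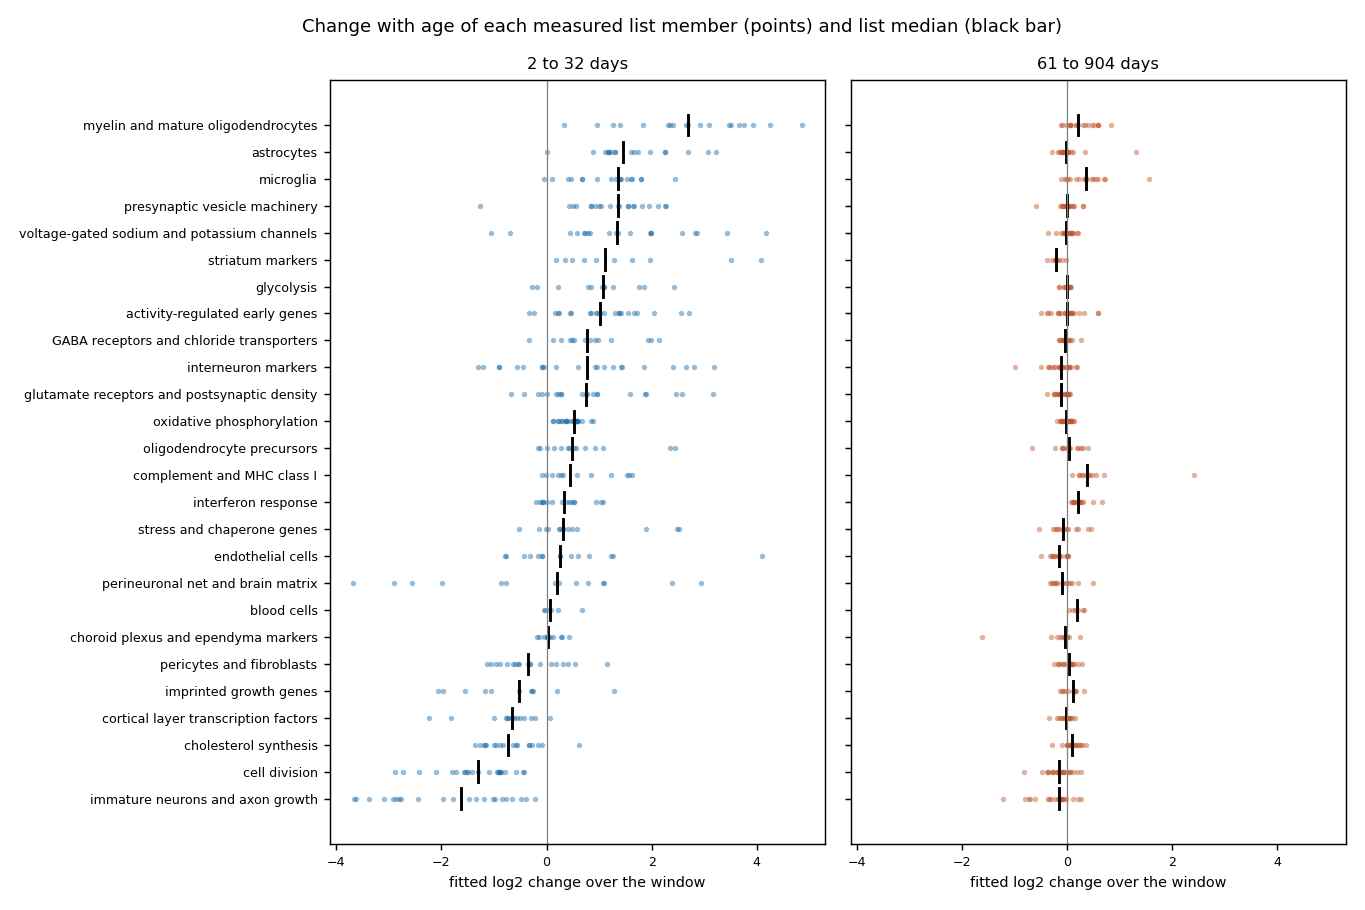
Fitted log2 change over 2 to 32 days (left, blue) and over 61 to 904 days (right, orange) for every measured member of 26 gene lists. Points are genes and black bars list medians; the myelin median is 2.69 in the left panel and 0.21 in the right, and the complement and MHC class I medians are 0.45 and 0.38.

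The slope difference asks whether genes changed at another rate after 61 days than before 32 days. Trim67 and Lamp5, at the 2 ends, had steep development slopes and adult slopes near 0. Trim67 had -1.165 ± 0.093 per doubling of age in development and 0.010 ± 0.106 in adults, a difference of 1.175 ± 0.141 (limma adjusted p = 0.000152). Lamp5 had 1.36 ± 0.08 and -0.05 ± 0.09, a difference of -1.41 ± 0.12 (limma adjusted p = 3.24e-05). Further genes at the positive end were B3gnt5, Mex3a, Stk32b, Vash2 and Tnc (1.10 to 0.87), and at the negative end Penk, Mag, Fam107a, Slco1a4 and Scn4b (-1.12 to -1.05). Differences also passed for Grin2a (-0.66 ± 0.06), Slc12a5 (-0.46 ± 0.04), Mbp (-0.82 ± 0.10), Dcx (0.61 ± 0.09) and Pvalb (-0.65 ± 0.15). C4b was steeper in adults, by 0.41 ± 0.11 per doubling (limma adjusted p = 0.0176), a call lost in 6 of 24 alternatives. Among these, the difference for C4b was 0.369 without the 32-day mouse (limma adjusted p = 0.0624) and 0.26 without the 904-day mouse (0.0922). Without the mice of 649 and 904 days it was 0.041 (0.832), and with age in days it was -0.0234 per day and passed with the opposite sign (0.0151). In all 4146 genes passed, 2010 positive and 2136 negative. The count was 2264 without the 61-day mouse, 1347 with that mouse among the immature ones, 547 without the mice of 61 and 904 days and 719 without those of 649 and 904 days. The calls of Penk, Mag and Pvalb were lost in the latter 2 settings and that of Dcx in the first of them.

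The stage contrast compares the 6 adult with the 6 immature mice. Il33 was higher in adults, at 8.89 ± 0.47 (SD, n = 6) against 6.11 ± 0.89 (n = 6), a difference of 2.78 ± 0.36 (limma adjusted p = 0.0123). Scn4b, the myelin-associated Ermn, the opioid precursor Penk, Fam107a and the prostaglandin synthase Ptgs2 were also higher, by 2.42 to 2.16. Cd24a, a surface protein of young neurons, was lower in adults by -3.00 ± 0.58, at 7.47 ± 0.26 against 10.47 ± 1.59 (SD, n = 6 each; limma adjusted p = 0.0166). The axon growth genes Dpysl3 and Dpysl5, the receptor Met, Trim67 and Tnc were lower by -2.85, -2.43, -2.49, -2.46 and -2.29. In all 3344 genes passed, 1671 higher and 1673 lower, of which 194 and 165 differed at least 2-fold.

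By list, 20 of 22 immature neuron genes and 12 of 23 cell division genes were lower in adults, and 12 of 18 cholesterol synthesis genes were, including Cyp51 (-0.91 ± 0.20) and Dhcr7 (-0.64 ± 0.12). Of 19 pericyte and fibroblast genes 10 were lower and 0 higher, with Nid1 at -1.12 ± 0.21 and Col3a1 at -0.83 ± 0.17. Of 19 myelin genes 7, including Trf (2.14 ± 0.46), and 7 of 12 complement and MHC genes, including B2m (1.17 ± 0.26), were higher. If adjusted over the list alone, 22, 20, 14 and 11 genes of the first 4 lists were lower and 1 pericyte and fibroblast gene, 13 myelin and 8 complement genes higher. Camera called 20 of 26 lists, these 6 with adjusted p of at most 2.74e-05. With an estimated correlation 0 lists passed, and each of the 6 had adjusted p = 0.409. Trends inside each stage count as spread here, and the number of called genes moved by over 1.5 times with any mouse left out. It was 1228 and 758 without 2-day replicates 1 and 2, 425 without the 5-day, 2075 without the 11-day, 5489 without the 20-day and 6072 without the 32-day mouse. Without the mice of 61, 122, 184, 365, 649 and 904 days it was 1503, 1193, 1389, 689, 530 and 928. With p adjusted over all probe sets 1844 genes passed. Without both 2-day mice 1 gene passed, and 0 passed with the 61-day mouse among the immature ones, without 649 and 904 days, or without 122 and 184 days. Among the genes at the ends, calls were lost in 4 (Il33, Cd24a, Met), 5 (Dpysl3), 6 (Ermn), 8 (Dpysl5), 12 (Tnc), 13 (Scn4b, Ptgs2) and 16 (Penk, Fam107a, Trim67) of 22 alternatives.

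Curvature asks which genes were lowest or highest at intermediate ages or levelled off. The highest positive coefficients were those of Trim67 (0.111 ± 0.017), B3gnt5, Mex3a, Stk32b, the heparan sulphate proteoglycan Gpc2 and Igfbpl1 (0.084 ± 0.004, limma adjusted p = 7.08e-07). The lowest were those of Lamp5 (-0.138 ± 0.015), Penk, Mag, Lynx1, Slco1a4 and Fam107a (-0.100 ± 0.017, limma adjusted p = 0.00134). Lamp5 levelled off more than it declined, with 10.99 at 61 days and 10.73 at 904 days. Gpr17, a receptor of differentiating oligodendrocyte precursors, was highest at 11 days (9.55) and had 7.92 at 904 days (curvature -0.049 ± 0.014, limma adjusted p = 0.0227). Its call was lost without 2-day replicate 1 (-0.047, limma adjusted p = 0.0598), replicate 2 (-0.038, 0.0887) or the 20-day mouse (-0.042, 0.0607). Presynaptic genes had negative curvature in 20 of 21 cases, channels in 17 of 20 and astrocyte genes in 15 of 18, and cell division and immature neuron genes positive curvature in 16 of 23 and 16 of 22. Their counts adjusted over the list alone were 20, 17, 16, 19 and 17. Camera called 20 of 26 lists, these 5 with adjusted p of at most 1.28e-09, and with adjusted p = 0.0762, 0.0762, 0.0997, 0.178 and 0.178 with an estimated correlation. In all 4000 genes passed, 1852 positive and 2148 negative, and with age in days 0 passed in limma, while 1888 had an unadjusted p under 0.05.

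The reversal share asks whether adult change ran against developmental change. Of the 7244 genes called in the development trend, 3199 (44.2%) had an adult slope of opposite sign and 4045 one of the same sign. Over 100 orders of the adult ages the share ran from 42.3% to 57.7%, and 22 orders lay at least as far from 50%. Sox4 and Dcx, which fell in development, had adult changes of -0.81 ± 0.16 and -0.37 ± 0.25, while Grin2a, which rose, had -0.15 ± 0.18; 0 of these adult changes passed in limma.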

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

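The tests of mixed RNA, of swapped samples, of the signal range of arrays and of the adult count's chance level, and the use of a binomial SD for Ttr, were chosen only after the result was seen. Of 60 comparisons of a single mouse with the other mice of its stage, 5 put that mouse far outside, where chance gives about 3 (1 in 20). No biological explanation was tested for the sex-linked signal.

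The first pattern is the sex-linked signal. In 2-day replicate 2, Xist was 5.67 and Eif2s3y, Kdm5d and Uty were 9.43, 8.60 and 8.95, each far from the 5 other immature mice, while all 12 mice are labelled male. A swap among the 12 mice is argued against, since it would keep the number of arrays with female-type signal at the labels' 0, and 11 had it. Mixing of male and female RNA is argued against, because the highest Y-linked excess on any of the 11 arrays over their median was 0.273 on the log2 scale. The RNA on these 11 arrays goes against the label male. Xist was at least 10.75 there, and Eif2s3y, Kdm5d and Uty reached at most 3.315, 4.813 and 3.977. How this mismatch arose stays open, including a wrong sex label for the mice. The test chosen for a wrong label compared 1 mouse with 1 mouse and did not decide. In it, X-linked genes active on both copies (Kdm6a, Eif2s3x, Kdm5c and Ddx3x) were higher in 2-day replicate 1 than in replicate 2. The median difference was 0.186, below the 0.2 and above the 0 set before the test.

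The second pattern is an axis of differences between arrays, taken from the residuals of the model with a slope for each stage. By construction it is unrelated to stage and to log2 age within each stage. It took 31.6% of the residual variance of unnamed probe sets and put the arrays of 20, 5, 365, 122 and 649 days and 2-day replicate 2 on one side. An array-wide change of signal range may account for it. The interquartile range of each array followed the axis score with r = 0.811 (permutation p = 0.0014) and rho = 0.860 (permutation p = 7e-04), the only relation tested. Without the 2 arrays farthest out r was 0.893. That range was taken over all probe sets, including the unnamed ones that define the axis. The 2 measures therefore share values, and the permutation p-values are not independent evidence for a change of signal range. The cell makeup of the tissue cannot be told apart from this, since the first axis in named genes took 29.0% of variance, close to the share in unnamed probe sets. As a covariate, the axis gave 7692 genes in the development trend and 1 in the adult trend. Because of how it was built, this covariate cannot change a slope of either trend, only the residual spread. It is therefore no check on those slopes.

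The third pattern is Ttr, a thyroid hormone carrier abundant in choroid plexus, at 10.05 in the 122-day and 8.38 in the 184-day mouse, against a median of 5.96 in the other adult mice. If choroid plexus tissue entered these pieces, its other genes could be highest at 122 days too; 2 of 8 were (Kl, by 0.82, and Kcnj13, by 0.55). The bound set before the test counted 3 or fewer as evidence against. The count of 2 lies below it by less than its binomial SD (1.22), and at least Kl is also expressed in neurons. At 122 days 7 of the 8 genes were above their median in the other adult mice. At 184 days only Clic6 was below it (-0.371), and Kl and Kcnj13 were above it by 0.214 and 0.516. In the other adult mice each of the 8 lay below the median of all signals (6.98). A small amount of choroid plexus tissue might therefore not make them highest, and the count decides nothing. A change of Ttr alone is not separated either, since the 8 genes were higher by a median of 0.185, between the 0.1 and 0.3 set. Both explanations stay open, and so does age, which was not tested.

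Other results are given as values. The mean signal of choroid plexus and ependyma markers was 6.17 in the 32-day mouse, against 6.06 to 6.10 in the other immature mice. Adult and development slopes differed in 4146 genes, tested as a contrast in limma. The differences at the ends were 1.175 for Trim67, 1.104 for B3gnt5, 0.988 for Mex3a, 0.904 for Stk32b, 0.874 for Vash2, 0.867 for Tnc, -1.41 for Lamp5, -1.12 for Penk, -1.094 for Mag, -1.077 for Fam107a, -1.063 for Slco1a4 and -1.047 for Scn4b. Among 11799 unnamed probe sets, which no gene comparison used, 1863 (15.8%) had a development trend, against 32.5% of 22961 named probe sets.

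Chance was set against each count by reordering the ages or splitting the mice 100 times, the real order included. Chance is unlikely, though not excluded, for the development trend (1 of 100 as large, real 7244, highest other 6750) and the stage contrast (1 of 100, 3344 and 2375). As the real order is included, 1 of 100 is the lowest possible result. For the slope difference (2 of 100, 4146 and 4237) and curvature (2 of 100, 4000 and 6965), another order called more genes than the real one. Reordering there also removed the development trend. It therefore tested whether age mattered at all, not whether slopes differed or curved given that trend. Chance is not excluded for the reversal share (88 of 100 as large as 44.16%, highest other 57.68%). For the adult trend the count decides nothing, since a real count of 0 makes 100 of 100 orders as large whatever they call (highest other 2). The 810 adult genes with an unadjusted p under 0.05 were reached by 27 of 100 orders, so chance is not excluded for that count.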

How the results depend on the processing

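Settings added after seeing the data are the array axis as covariate and those without 649 and 904 or 122 and 184 days, and list tests without single mice. The axis covariate leaves the slopes of both trends unchanged by construction, so its counts there differ only through the residual spread. The development trend stayed within 1.5 times of 7244 genes in the settings that count genes (5094 to 7692; leaving out single mice 6044 to 7165), and it called 9315 of all 34760 probe sets. The reversal share ran from 42.66% to 46.74%. The adult trend called 0 genes, and 3 after quantile normalization again, 2 with the dimmest genes dropped, 1 with eBayes trend and robust, 528 with array weights, 3 with age in days, 1 with the array axis as covariate and 0 to 5 leaving out single mice. The slope difference (4146) became 6380 with age in days, 1347 with the 61-day mouse among the immature, 547 without 61 and 904 days, 719 without 649 and 904 days, and 2264 to 4183 leaving out single mice (2264 without the 61-day mouse). The stage contrast (3344) became 6551 with array weights, 0 with the 61-day mouse among the immature, 1 without both 2-day mice, 1844 with p adjusted over all probe sets (2400 probe sets in all), 0 without 649 and 904 days, 0 without 122 and 184 days, and 425 to 6072 leaving out single mice. Curvature (4000) became 0 with age in days, which spreads the oldest mice far from the rest, and 2938 to 4181 leaving out single mice. List calls with an estimated correlation were 0 in development (from 20), 0 in the adult trend (from 10), 0 in the stage contrast (from 20) and 0 in curvature (from 20). Adult list calls were 1 without 649 and 904 days, 6 without 904 days, 9 without 122 and 184 days (myelin lost, 0.094) and 11 without 2-day replicate 2. Settings with fewer mice test with fewer residual degrees of freedom; beyond that the cause was not tested. Signs turned for Xist without 2-day replicate 2, the mouse with Y-linked signal (development -0.92, slope difference 0.343, curvature 0.033; without replicate 1, 4.264, -0.953 and -0.113). With age in days they turned for C4b (slope difference -0.0234003 per day, adjusted p = 0.0151, curvature -5e-07) and Gpr17 (curvature 3e-06), and without 649 and 904 days for the adult change of striatum markers (0.12). Over all named genes and settings 12092 values kept sign and call, 1319 lost the call, 155 gained it, 109 changed sign with no call in either, and 6 changed sign with a call in at least 1. No paired analysis was possible because the ages share fewer than 2 replicate numbers. Dim probe sets have no detection call here, so changes near the arrays' background are limited by background signal of unknown level.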

Other observations

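The tests of peak ages and of genes highest at 11 and 20 days were chosen after their values were seen. A group of genes was highest around the onset of myelination. In the 11- and 20-day mice, 7 genes exceeded every other mouse except the 32-day one by more than 0.5 on the log2 scale. These were Enpp6 and Gpr17, both genes of oligodendrocytes before or during myelination, the hyaluronan-binding gene Cemip, the matrix genes Hapln1 and Npnt, Ccn3 and Nek10. Enpp6 had a mean of 5.77 at 2 and 5 days, 7.97 at 11 and 8.13 at 20 days, and a mean of 6.91 from 61 to 904 days. Hapln1, a link protein of perineuronal nets, had 6.483, 9.003, 8.373 and 7.505. Of 55 pairs of mice, 3 had as many such genes, this one and 2 pairs of mice aged 2 to 5 days (32 and 23 genes), and the highest of 15 adult pairs had 1. Most pairs join ages that are not neighbours, where a smooth time course leaves few such genes. The share of pairs therefore does not measure how unusual 7 genes are.

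The hypothesis that markers of newly forming oligodendrocytes peak before myelin genes was left open. Of 4 markers, 3 were highest at an earlier age than the myelin list's median peak age of 904 days: Gpr17 and Neu4 at 11 days and Enpp6 at 20 days, while Bcas1 was highest at 904 days. The median is the last age sampled, so almost any gene peaks earlier, and it hides a split: 10 of the 19 myelin genes were highest at 904 days, 7 at 20 days and 2 at 32 days. Enpp6 was therefore not earlier than those 7, and the comparison does not settle the order. Each age rests on 1 mouse, so a peak age has no replicate check.

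Because Pcdhb2 led the adult trend, it was asked whether the protocadherin beta cluster, a tandem family of neuronal adhesion genes, may have risen with adult age as a group. Of the other 21 measured Pcdhb genes, 21 (100%) had a positive adult slope, with a median change of 0.65 over 61 to 904 days and a range from 0.016 to 1.098. Camera gave p = 1.85e-28 with the preset correlation and p = 0.00434 with an estimated correlation. By limma 0 of the 21 passed over all genes and 14 had an unadjusted p under 0.05. Without the mice of 649 and 904 days 19 of 21 were positive, with a median of 0.35, the slope being scaled to the full window of 61 to 904 days. These genes are close in sequence, and signal shared between their probes was not tested, so fewer than 21 independent changes could give this pattern.

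A similar hypothesis came from Manf and Pdia4. Of 13 other chaperones and folding enzymes of the endoplasmic reticulum, 13 (100%) had a negative adult slope, with a median of -0.27 and a range from -0.528 to -0.011; Hspa5, the main chaperone of this compartment, had -0.53 ± 0.13. Camera gave p = 4.36e-14, and p = 0.0109 with an estimated correlation, which was 0.406. Again neither p was adjusted over lists. By limma 0 passed over all genes and 6 had an unadjusted p under 0.05. Without the mice of 649 and 904 days 12 of 13 were negative, with a median of -0.20, again scaled to the full window. The group may decline with adult age, as a hypothesis found and tested on the same 6 adult mice.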
